A study of Arabidopsis thaliana with 16 samples.

How the data were processed

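Total RNA from seedlings of Arabidopsis thaliana in the Col-0 background was hybridised to 16 single-colour Affymetrix ATH1 arrays, 1 array per sample. The plants carried an estradiol-inducible artificial microRNA aimed at the TOR kinase gene (amiR-tor, lines 9, 17 and 20) or the empty inducible vector pER8. The labels disagree in places: the series title names another gene, every sample description mentions the empty vector, and a tag of the empty-vector samples mentions an artificial microRNA. The groups were taken from the sample titles, with which the source names and genotype tags match, and what every comparison means rests on them. Seedlings of 2 weeks were moved to plates with 20 µM estradiol or without it and harvested after 3 or 6 days, per the labels' protocols. The amiR-tor arrays formed 4 groups of 3 (induced and non-induced, 3 and 6 days), with the 3 lines as replicates, and each of the 4 empty-vector conditions had 1 array. Wild-type seedlings and the 0 day harvest that the protocols mention were not analysed here. Nothing in the labels says whether the seedlings of a line came from separate cultures, so p-values measure the spread between lines within a group. In the non-induced 3 day and induced 6 day groups, line 9 also differed from the other lines in the kind of array described in the Results. The spread there mixes line and kind of array.

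The deposited values are on a log2 scale and were made by the authors with GCRMA, which corrects the background, normalizes across arrays and summarises each probe set, per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited log2 values ran from a floor of 2.12 to 15.32 over 22810 probe sets. The array medians lay between 5.60 and 5.67, and between 30.2% and 31.3% of the probe sets of an array lay within 0.1 of the floor, where differences are compressed. Arrays give no counts, so their number limits the precision. No values were normalized again for the main results.

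Left out were 64 control probe sets and 9045 dim probe sets that did not reach a log2 value of 4 in at least 3 arrays, which left 13701. The table of probe set names used here covers part of the array: of the 22746 probe sets of genes, 13513 were listed with 1 gene, 503 with several and 8730 were not listed. Gene identifiers were updated through the RefSeq gene table of the TAIR10.1 assembly, which matched 7333 of the kept probe sets to a locus and 1066 to a symbol other than the locus tag; unlisted probe sets are given by their array identifier, and no coordinates are given because the array's own build is not stated. No probe set was listed for TOR itself, so the level of the targeted transcript was not analysed here. A gene with several probe sets was represented by the one with the highest mean.

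All 16 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group), which left 8 residual degrees of freedom, and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05 over the kept probe sets. An empty-vector group has 1 array, so its array was assumed to vary like the amiR-tor arrays. Differences between lines in the induction effect were tested on the 12 amiR-tor arrays with the 2 days as repeats. Gene lists fixed by locus were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists within a contrast, with an estimated correlation and fry beside it. Of 443 loci on 22 lists, 90 were on a named probe set and 82 were kept; 11 lists had at least 3 genes and were tested. The lists for nitrogen assimilation, salicylate defence and floral markers had 0 kept genes, and lists of ribosomal proteins were left out because the gene table holds no product descriptions. Families of at least 8 genes with the same leading letters in their symbols, and the genes encoded in the plastid, were tested in the same way; these sets were chosen after the data were seen but before any was tested.

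Genes were named by a rule set before the data were examined: the 10 largest rises and falls among called probe sets with a gene symbol that moved the same way in every line (for both days, in all 6 pairs of arrays), or, where none passed, the 5 largest each way by limma's moderated statistic, and 5 each way for the other comparisons. In each list up to 4 members past the threshold were named, or up to 2 with the smallest p, given as values. Genes named outside the rule are said to be so.

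The same line by label contributed an induced and a non-induced array at each day, so the lines pair the arrays. Deviations of same-line arrays from their group means correlated between -0.63 and 0.45 for line 9, between -0.16 and 0.17 for line 17 and between -0.15 and 0.52 for line 20. The fit with the line as a block was an alternative. No 2 arrays looked like copies: the highest correlation was 0.992, with 4.48% identical values.

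Alternatives were no filter and a stricter filter at log2 6, quantile normalization on top, centring each array on its median, eBayes with trend and robust, the line as a block, leaving out each line, fits of the compared arrays alone, averaging the days, and a 2-fold requirement. After the control probe sets had been seen, fits were added with the 25S class of the array (25S control probe set under or over log2 9) as a covariate, with that class and the line block, without line 9 but with the line block, and on the 10 arrays with high 25S signal. Induction at 3 days, at 6 days, over both days and its difference between the days, the days without inducer, and the lists at 6 days and over both days were checked against other splits of the amiR-tor arrays, at most 100 drawn with a fixed seed. Comparisons with the empty vector were not.

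The scripts were tested on simulated arrays built from the real means and spreads of the 13701 probe sets. For induction over both days, 74.6% of 67 probe sets changed by 1 log2 unit, 95.5% of 67 changed by 2 and 98.5% of 66 changed by 3 were recovered, with 4 calls among 13485 unchanged ones. For induction at 6 days the recovered shares were 47.8%, 94.0% and 97.0%, with 10 calls among unchanged probe sets, and for induction at 3 days 46.3%, 91.0% and 97.0%, with 8. For line 20 minus line 17 they were 0%, 34.3% and 69.7%. For induction over both days, a simulated list of 16 genes shifted by 0.5 was called and 0 of 20 unshifted lists were. The simulation had no 25S classes and drew each probe set independently. It therefore does not test the list calls for genes that vary together. Figures were drawn with matplotlib 3.10.9.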

Results

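Gene expression was measured in seedlings in which an artificial microRNA against the TOR kinase, a central regulator of growth by nutrients, could be switched on with estradiol. The 16 arrays comprised 3 amiR-tor lines (9, 17 and 20) with and without inducer at 3 and 6 days, and the empty vector under the same 4 conditions with 1 array each. The comparisons ask what changed when the microRNA was induced, when estradiol was given without it, between days, and between lines. No probe set was listed for the targeted transcript in the names used here, so how far TOR was silenced in any line was not checked.

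The arrays fell into 2 kinds that the labels do not name. The 25S ribosomal RNA control probe set read 5.27 to 6.66 (log2) on 6 arrays and 11.38 to 11.99 on the other 10. On the same 6 arrays the 5′ actin control probe set minus the 3′ one was -10.39 to -4.47 on the log2 scale, against -1.92 to -1.43 on the other 10. The 6 arrays were both induced arrays of line 9 and all 3 day arrays of lines 17 and 20. The first principal component, with 44.8% of the variance, separated the 2 kinds. In line 9 induction therefore cannot be told apart from the kind of array, whereas each pair of lines 17 and 20 lay within 1 kind; at 3 days the actin difference of line 17 still moved from -4.47 without inducer to -8.58 with it.

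**Figure D1:**
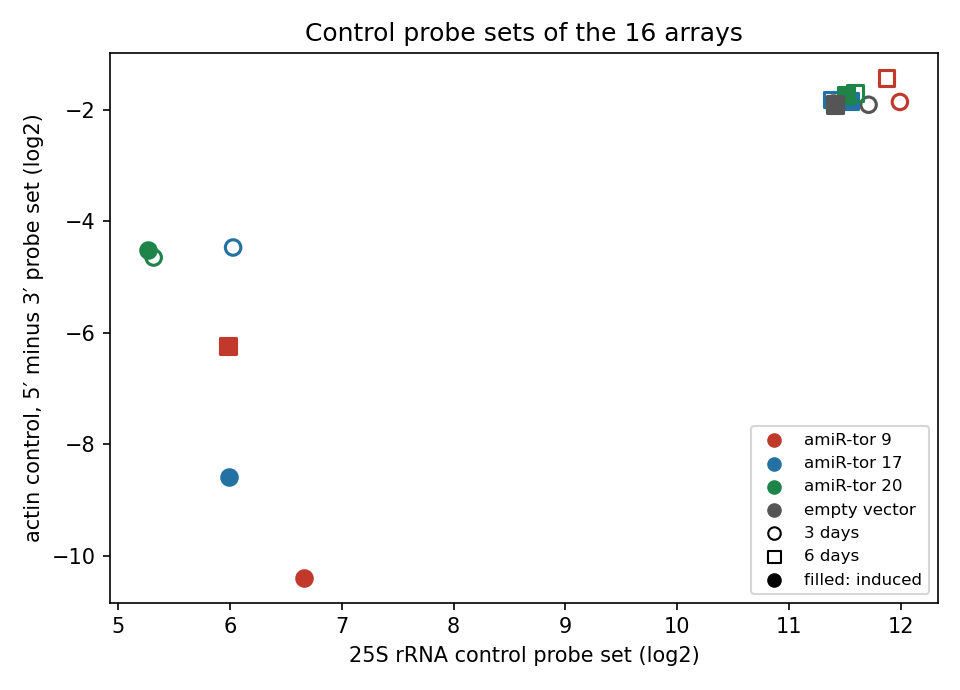
Control probe sets of the 16 arrays: the 25S ribosomal RNA probe set (log2, horizontal) against the 5′ minus 3′ difference of the actin control (log2, vertical), 1 point per array, colour for the line, shape for the day, filled when induced. The 6 arrays at 5.27 to 6.66 all have an actin difference of -4.47 or lower, and the other 10 lie between -1.92 and -1.43.

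After 6 days of induction, 2 genes of anthocyanin synthesis had the largest rises among the 4 named genes that passed. DFR (AT5G42800), the dihydroflavonol reductase of the pathway, rose from 2.76 ± 0.27 (SD, n = 3) to 7.90 ± 1.4 (SD, n = 3), a change of 5.14 ± 0.60 (SE; limma, Benjamini-Hochberg adjusted p = 0.0085). UF3GT (AT5G54060), a glycosyltransferase of anthocyanins, rose by 3.59 ± 0.52 (SE; limma adjusted p = 0.0196), and ATG8H (AT3G06420), a ubiquitin-like protein of autophagosomes, rose by 1.74 ± 0.31 (SE; limma adjusted p = 0.0439). AAE16 (AT3G23790), of the acyl-activating enzyme family, rose by 1.68 ± 0.25 (SE; limma adjusted p = 0.0202). Without inducer the means of DFR and UF3GT in the lines lay under the log2 value of 4 that defined dim probe sets, so their changes are measured from levels not shown to be above background. In the empty vector DFR differed by -0.08 at 3 days and 0.48 at 6 days, and ATG8H by 0.16 and -0.05.

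Over all 13701 probe sets, 54 rose and 9 fell at 6 days (limma, Benjamini-Hochberg adjusted p under 0.05). Without line 9 the count was 9, with 7 of the 63 among them, without line 17 it was 1 and without line 20 it was 55. On the 10 arrays with high 25S signal it was 0, and with the 25S class as a covariate it was 30. The class covariate can also take up a response particular to line 9. In the fit without line 9, the values of DFR and UF3GT were 4.64 ± 0.53 and 3.39 ± 0.44 (SE), with limma adjusted p = 0.069 and 0.0873.

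At 3 days no probe set passed the threshold in limma, where 1782 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0527. The named genes with the largest moderated statistics, none of them past the threshold, had positive differences for NQR (AT3G27890, a quinone reductase, 0.77 ± 0.15 SE), scpl48 (AT3G45010, 1.27 ± 0.25), XPO1B (AT3G03110, 0.65 ± 0.16), ETFALPHA (AT1G50940, 0.62 ± 0.16) and AER (AT5G16970, an alkenal reductase, 0.98 ± 0.26). Negative differences were those of P1R3 (AT3G29370, -1.55 ± 0.36), UGT85A4 (AT1G78270, -1.25 ± 0.32), PORB (AT4G27440, -1.37 ± 0.36), UGT72E1 (AT3G50740, -2.29 ± 0.64) and IGPD (AT3G22425, -0.91 ± 0.28). At 3 days DFR differed by 1.88 ± 0.60 (SE; limma adjusted p = 0.353) and UF3GT by 0.52 ± 0.52 (SE).

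Over both days together DFR again had the largest named rise. It rose by 3.51 ± 0.42 (SE; limma, Benjamini-Hochberg adjusted p = 0.00885) and UF3GT rose by 2.06 ± 0.37. SAG29 (AT5G13170), a sugar transporter of senescing leaves, rose by 3.15 ± 0.62, SWEET10 (AT5G50790), another member of the SWEET transporter family, by 1.71 ± 0.36, and APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, by 2.03 ± 0.37. The protease genes SBT3.5 (AT1G32940) and ALPHA-VPE (AT2G25940), a vacuolar processing enzyme, rose by 1.30 ± 0.23 and 1.2 ± 0.27. AR791 (AT1G52080), ATG8H and AAE16 rose by 1.62 ± 0.28, 1.23 ± 0.22 and 1.18 ± 0.18 (SE). For these 10 genes the limma adjusted p ran from 0.00885 to 0.0453, and the naming rule required each to be higher in all 6 pairs. Without inducer the means of ALPHA-VPE at both days and of SWEET10 at 6 days also lay under the log2 value of 4 that defined dim probe sets.

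The 8 named falls over both days included enzymes of chlorophyll synthesis. PORB, a protochlorophyllide oxidoreductase, fell by 1.44 ± 0.25 (SE; limma, Benjamini-Hochberg adjusted p = 0.021), and HEMB1 (AT1G69740), a dehydratase of tetrapyrrole synthesis, fell by 0.56 ± 0.13. GID1C (AT5G27320), a gibberellin receptor, fell by 0.93 ± 0.22, TUB5 (AT1G20010), a beta-tubulin, fell by 0.69 ± 0.16 and PRL (AT4G02060), a subunit of the replication licensing complex, fell by 0.67 ± 0.15. Fes1B (AT3G53800) fell by 1.57 ± 0.37, TBL36 (AT3G54260) by 1.08 ± 0.19 and UGT85A4 by 1.02 ± 0.23 (SE). The induced means of Fes1B, 3.02 and 2.71 at 3 and 6 days, lay under the log2 value of 4, so the size of its fall is measured to a level not shown to be above background. The limma adjusted p of the 8 ran from 0.0199 to 0.0494, and the rule required each to be lower in all 6 pairs. PORB also differed by -1.08 and -0.24 in the empty vector at 3 and 6 days, Fes1B by -1.32 and -0.77 and SAG29 by 1.04 and 0.93. With the line as a block the limma adjusted p of Fes1B was 0.0529 and that of GID1C 0.0573.

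In all, 304 probe sets rose and 86 fell over both days (limma, Benjamini-Hochberg adjusted p under 0.05); 201 of the 390 had a locus and 42 a symbol. This fit counts the 2 days of a line as separate replicates, and averaging the days per line first gave 0 calls in limma, with 1992 at an unadjusted p under 0.05. The count was 6 without line 9, 1 without line 17, 379 without line 20, and 61 with the 25S class as a covariate, where DFR and AAE16 were past the threshold among the 18 genes named above. In that fit the other 16 had limma adjusted p = 0.0634 to 0.166 with the same directions, such as 3.01 ± 0.71 for SAG29, 1.83 ± 0.41 for APL3, 1.67 ± 0.32 for UF3GT and -1.21 ± 0.25 for PORB (SE). Among genes without a symbol, chosen after their values were seen, AT1G09500 rose by 3.11 ± 0.46 and AT1G10585 by 2.34 ± 0.31 (SE), while AT3G62950 fell by 2.17 ± 0.40 and AT3G16670 by 1.96 ± 0.26. AT5G59845 rose by 3.08 ± 0.68 (SE), and differed by 2.3 and 3.19 in the empty vector at 3 and 6 days.

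**Figure D2:**
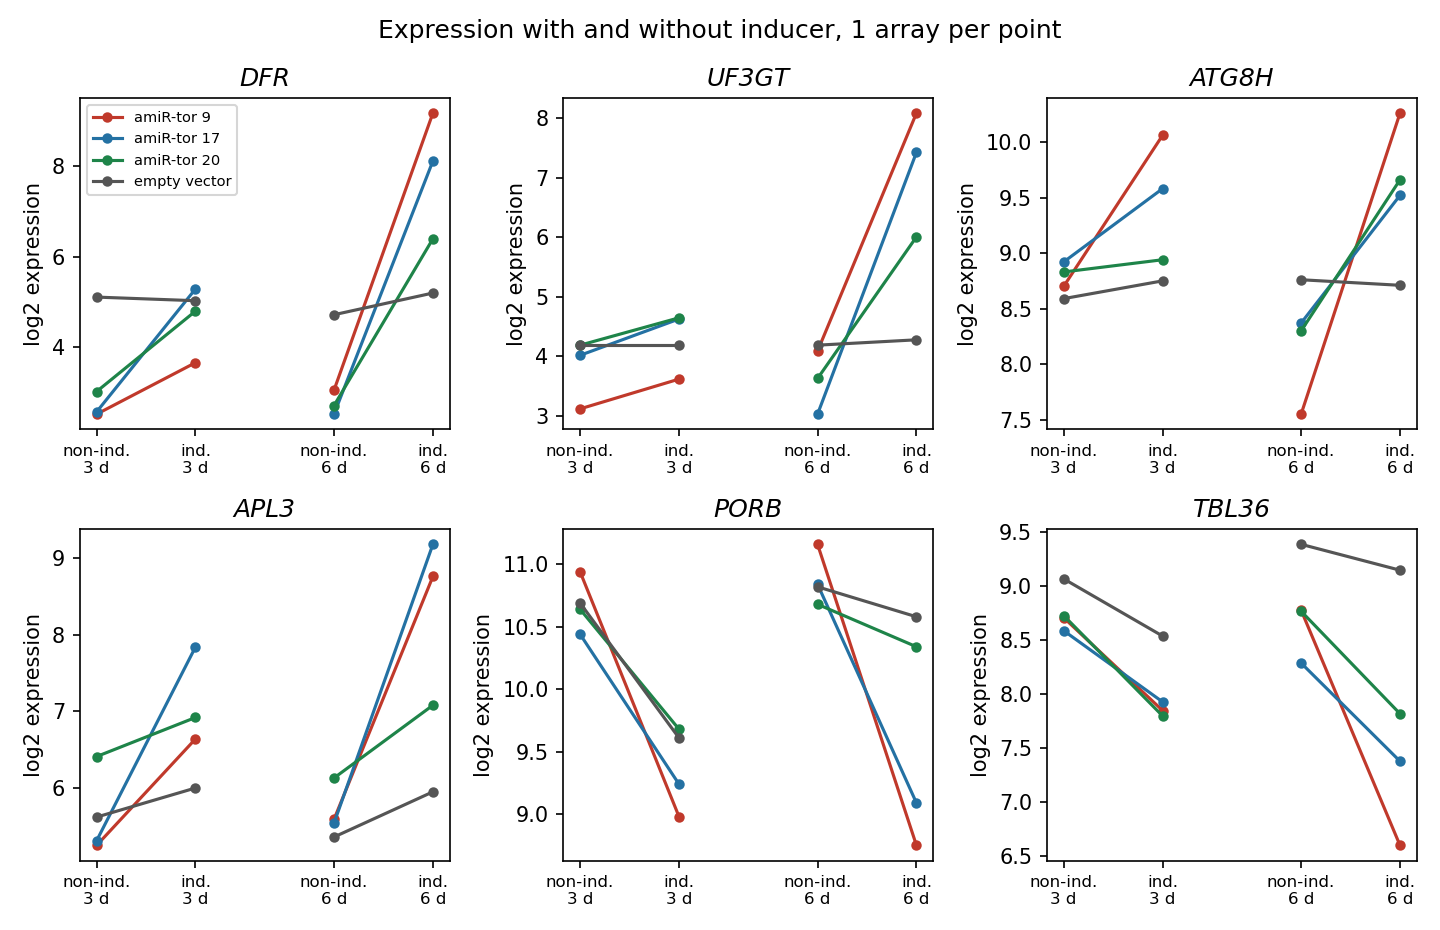
Expression (log2) of DFR, UF3GT, ATG8H, APL3, PORB and TBL36 without and with inducer at 3 and 6 days; each point is 1 array and each line joins the non-induced and induced arrays of an amiR-tor line or the empty vector. DFR changed by 6.13, 5.60 and 3.69 in lines 9, 17 and 20 at 6 days and by 0.48 in the empty vector.

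Of 16 loci on the flavonoid list, 4 were on a named probe set and 3 were kept, so most of the list was not assessed. All 3 rose over both days, also when adjusted over the list alone. They were DFR, UF3GT and UGT78D2 (AT5G17050, a flavonoid glucosyltransferase), the last by 1.05 ± 0.19 (SE). With the 25S class as a covariate 1 of the 3 passed, DFR, and the values of UF3GT and UGT78D2 were 1.67 ± 0.32 and 0.83 ± 0.16 (SE). The list as a set was higher over both days (limma camera adjusted p = 0.000353) and at 6 days (camera adjusted p = 5.07e-06), with adjusted p = 0.335 and 0.143 with an estimated correlation. At 3 days the camera adjusted p was 0.0791, and 0.00964 without line 9. In the main fit with an estimated correlation the 3 day camera adjusted p of the list was 0.444. Its median change was 0.93, 1.09 and 0.49 in lines 9, 17 and 20 at 3 days, 4.0, 4.40 and 2.38 at 6 days, and 0.00 and 0.19 in the empty vector.

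Of 39 autophagy loci 16 were kept. Of these 16 genes, 4 rose over both days and 12 did not pass, or 9 and 7 adjusted over the list alone. With the 25S class as a covariate 0 of the 16 passed singly in limma, while the camera adjusted p of the set was 9.6e-05 and its median 0.30. The values of ATG8H, ATG8G, APG8A and AT3G59950 were then 1.08 ± 0.23, 0.66 ± 0.18, 0.64 ± 0.16 and 0.52 ± 0.13 (SE). Without that covariate ATG8H rose by 1.23, ATG8G (AT3G60640) by 0.83 ± 0.19, APG8A (AT4G21980) by 0.73 ± 0.15 and AT3G59950, an ATG4-type protease, by 0.62 ± 0.13 (SE). The other 12 ranged from ATG3, at -0.46, to ATG8D, at 0.69, both not past the threshold, and 15 of the 16 had a positive value. The set was higher over both days (limma camera adjusted p = 0.000353), at 6 days (4.2e-05) and at 3 days (0.0382), with adjusted p = 0.335, 0.289 and 0.495 with an estimated correlation. Without line 17 the camera adjusted p at 3 days was 0.0738. The median over both days was 0.36, and 0.235 without line 9. By pair it was 0.20 to 0.50 in the 4 pairs of lines 17 and 20, 0.72 and 0.70 in line 9, where the kind of array changed, and 0.08 and -0.06 in the empty vector. With the line as a block the limma adjusted p of ATG8G was 0.0535. Without line 9 the values of ATG8H, ATG8G, APG8A and AT3G59950 over both days were 0.82, 0.49, 0.53 and 0.465.

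Among the 9 kept of 48 nuclear photosynthesis loci none passed singly. The set was lower at 6 days (limma camera adjusted p = 0.0206, median -0.21) and not past the threshold over both days (camera adjusted p = 0.0772). At 6 days its camera adjusted p was 0.482 with an estimated correlation, and the unadjusted P value of fry was 0.108. LHCB4.2 and LHCB4.1 had values of -0.22 and -0.25 over both days. Without line 17 the camera adjusted p at 6 days was 0.294, and without line 9 that over both days was 0.0389. In the main fit with an estimated correlation the camera adjusted p over both days was 0.577. Among the 4 kept of 22 senescence loci SAG29 rose and 3 did not pass, and the set had camera adjusted p = 0.212. Among the 4 kept of 25 starch loci APL3 rose and 3 did not pass, or 3 rose adjusted over the list alone, with camera adjusted p = 0.0772. Without line 9 it was 0.0389 and without line 20 0.0489, and at 6 days it was 0.061, or 0.0374 without line 20. In the main fit with an estimated correlation the camera adjusted p of the starch list was 0.335 over both days and 0.289 at 6 days.

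The other tested sets were not past the threshold over both days or at 6 days. Their kept genes were also only a part of each list, such as 9 of 33 cell wall loci and 6 of 24 sugar starvation loci. Of 9 cell wall genes, EXPB3 had a value of -1.65 and XTH33 of 1.1, and the set's camera adjusted p was 0.0832, with 1 rise and 4 falls adjusted over the list alone. Its median was -2.27 and -1.46 in line 9, where the kind of array changed, but -0.43 to -0.22 in lines 17 and 20. The 6 sugar starvation genes (AKINBETA1 -0.77, ETFQO -0.55) had camera adjusted p = 0.132, with 2 falls adjusted over the list alone. Without line 20 it was 0.0198 over both days, 0.0246 at 6 days and 0.0484 at 3 days. In the main fit with an estimated correlation the camera adjusted p was 0.581 over both days, 0.562 at 6 days and 0.677 at 3 days. The 4 dehydration genes (COR15A 1.62, LTI30 0.55), of which 2 rose adjusted over the list alone, had camera adjusted p = 0.304. At 6 days it was 0.128, or 0.0305 without line 20, and 0.388 in the main fit with an estimated correlation. The 8 ribosome biogenesis genes (AT3G15460 0.43, AT2G40360 0.24) had camera adjusted p = 0.439, the 3 root markers (PYK10 -0.20) 0.355 and the 4 housekeeping genes (AT2G28390 0.18) 0.461. For the housekeeping genes, a control list, the unadjusted P value of limma's fry over both days was 0.0223 (up). At 6 days the root markers had a median of 0.03 while the test pointed down.

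Lists with 1 or 2 kept genes were not tested as sets. PRL, from the DNA replication list, fell as given above. Values over both days were 0.26 for RAPTOR1, a partner of TOR, -0.14 and -0.16 for the mitotic kinases AUR1 and AUR2, -0.23 for COB in cellulose synthesis, 0.80 and 1.2 for the jasmonate-linked PDF1.2 and THI2.1, 0.86 and 0.14 for the auxin-responsive WES1 and GH3.3, 0.28 and -0.25 for the cytokinin regulators RR16 and ARR15, and 0.09 for the clock gene GI. None of these had limma adjusted p under 0.05.

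**Figure D3:**
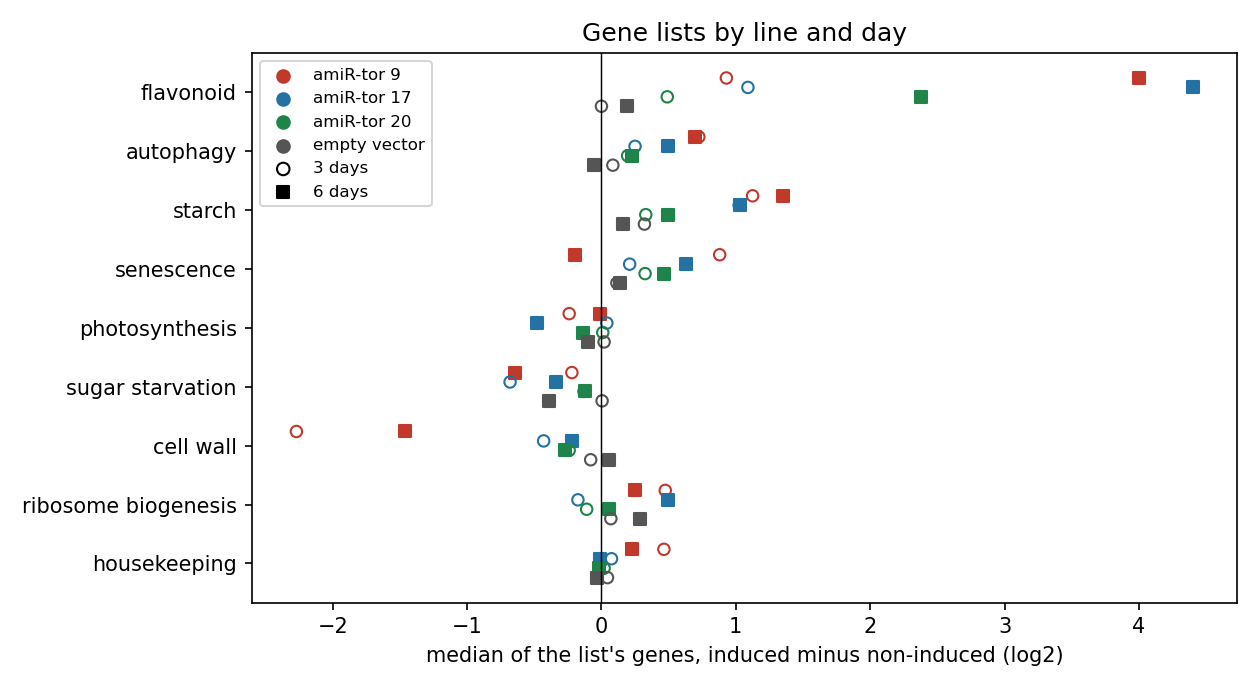
Median log2 difference, induced minus non-induced, of the genes of 9 fixed lists, by line (colour) and day (open circles 3 days, filled squares 6 days); each point is a median over the list's genes in 1 pair of arrays. The flavonoid list lies at 2.38 to 4.40 in the 3 lines at 6 days and at 0.19 in the empty vector.

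Induction at 6 days was set against induction at 3 days by a test of the difference itself. By moderated statistic the first named positive differences were those of UF3GT and DFR, 3.07 ± 0.73 and 3.26 ± 0.85 (SE), BETA-VPE (AT1G62710), a vacuolar processing enzyme, at 1.34 ± 0.35, AAE16 at 1.01 ± 0.35 and NDB2 (AT4G05020) at 0.70 ± 0.28. On the negative side stood XPO1B (-0.61 ± 0.22), PIFI (AT3G15840, -0.53 ± 0.20), CSLA03 (AT1G23480, -0.66 ± 0.25), MAP1D (AT4G37040, -0.62 ± 0.26) and ADPG1 (AT3G57510, -1.0 ± 0.44). No probe set passed in limma, with 234 at an unadjusted p under 0.05. The flavonoid list was higher at 6 than at 3 days (limma camera adjusted p = 3.72e-06; adjusted p = 0.135 with an estimated correlation).

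Estradiol in the empty vector, the control for the inducer, gave no call in limma, with 111 probe sets at an unadjusted p under 0.05. The genes named by their moderated statistic over both days, not by the size of the difference, were LCR68 (AT2G02130, 0.65 ± 0.27 SE), AGL42 (AT5G62165, 0.93 ± 0.39), PDF2.1 (AT2G02120, 0.74 ± 0.33), TRM28 (AT5G03670, 0.78 ± 0.34) and PRN (AT3G59220, 0.62 ± 0.28) upward, and ADPG1 (-1.35 ± 0.38), OSM34 (AT4G11650, -0.91 ± 0.30), PRX52 (AT5G05340, a peroxidase, -1.99 ± 0.69), CHI (AT2G43570, -1.44 ± 0.58) and HSA32 (AT4G21320, -0.37 ± 0.15) downward, none past the threshold. The share of probe sets at an unadjusted p under 0.05 was smaller than chance alone would give. The spread in this test came from the amiR-tor arrays, whose non-induced 3 day and induced 6 day groups mixed the 2 kinds of array. The empty-vector arrays were all of 1 kind, so the absence of calls does not show that estradiol did little. Across probe sets, which are not independent replicates, changes over both days in the amiR-tor lines and the empty vector correlated at r = 0.15 (Spearman 0.168). No arrays were shared.

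Induction in the amiR-tor lines minus estradiol in the empty vector passed for 1 probe set in limma, 252984_at, which has no listed gene. It was higher by 2.64 ± 0.28 (SE; Benjamini-Hochberg adjusted p = 0.0199), with changes of 1.44 to 3.82 in the 6 amiR-tor pairs and of 0.11 and -0.16 in the empty vector. The count was 0 when any 1 of the 3 lines was left out, with the line as a block and with the 25S class as a covariate. Genes named by their moderated statistic were not past the threshold: SBT3.5 (1.94 ± 0.45 SE), DFR (3.31 ± 0.85), JRG21 (AT3G55970, 2.75 ± 0.73), AAE16 (1.29 ± 0.35) and ALPHA-VPE (1.98 ± 0.54) had positive differences, and scpl42 (AT5G42240, -0.83 ± 0.28), TUB5 (-0.89 ± 0.32), PRL (-0.82 ± 0.30), SQN (AT2G15790, -1.02 ± 0.43) and ATERDJ2B (AT4G21180, -0.56 ± 0.24) negative ones. For JRG21, ALPHA-VPE and SBT3.5 part of the difference came from the single empty-vector pair at 6 days. Without and with estradiol it read 7.58 and 5.46, 5.11 and 3.46, and 8.65 and 7.16 (log2). For DFR and AAE16 the same pair read 4.72 and 5.20, and 4.97 and 4.82. The autophagy and flavonoid lists were higher (limma camera adjusted p = 0.000256 and 0.000225), with adjusted p = 0.469 and 0.304 with an estimated correlation.

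Without inducer, the amiR-tor lines and the empty vector differed at no probe set in limma (664 at an unadjusted p under 0.05). DFR was nevertheless lower in value by -2.18 ± 0.60 (SE; adjusted p = 0.813), with 5.11 and 4.72 in the non-induced empty vector at 3 and 6 days against means of 2.70 and 2.76 in the lines. SGP2 (AT3G21700, -0.84 ± 0.14), CHI (-1.59 ± 0.47), ARR15 (-0.46 ± 0.15) and PRX52 (-1.75 ± 0.56) were the other named negative differences, and SCL21 (AT2G04890, 0.62 ± 0.15), TRM20 (AT4G28760, 0.81 ± 0.20), CAF1 (AT2G20020, 0.67 ± 0.17), ATERDJ2B (0.65 ± 0.17) and TRM28 (0.98 ± 0.28) the positive ones. The cell wall list was lower in the lines (camera adjusted p = 0.00694, and 0.237 as the adjusted p with an estimated correlation), and so was the flavonoid list (0.0281, and adjusted p = 0.562 with an estimated correlation). With the 25S class as a covariate the camera adjusted p of the cell wall list was 0.133; without lines 9 and 17 in turn that of the flavonoid list was 0.116 and 0.092, and without line 9 the count of probe sets was 33.

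Between 3 and 6 days without inducer no probe set passed in limma (928 at an unadjusted p under 0.05). The named differences were STZ (AT1G27730, a zinc-finger stress regulator, 2.57 ± 0.54 SE), CYP71B26 (AT3G26290, 0.92 ± 0.23), PIFI (0.52 ± 0.14), GID1C (1.09 ± 0.30) and bZIP58 (AT1G13600, 0.76 ± 0.24), higher in value at 6 days, and P1R3 (-1.99 ± 0.36), BRH1 (AT3G61460, -0.76 ± 0.18), TRM20 (-0.74 ± 0.20), PDF2.1 (-0.95 ± 0.27) and UBP15 (AT1G17110, -0.78 ± 0.23), lower in value. Without line 9 the count was 310 (219 higher and 91 lower), and in that fit the 2 days and the 2 kinds of array coincide. In the main fit they also coincide for lines 17 and 20, and only the arrays of line 9 are of 1 kind. The named differences are therefore not shown to be effects of time.

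The lines differed in how many probe sets differed in value with induction. In line 9, 2999 probe sets at 3 days and 2733 at 6 days differed by at least 2-fold between the induced and non-induced array, against 742 and 1112 in line 17, 172 and 253 in line 20, and 132 and 197 in the empty vector. Across probe sets, which are not independent replicates, the changes averaged over the days correlated at r = 0.548 between lines 9 and 17 (Spearman 0.524), 0.249 between lines 9 and 20 (0.223) and 0.526 between lines 17 and 20 (0.517), with no arrays shared. By pair, the 3 day change of line 17, over which its actin difference moved from -4.47 to -8.58, correlated with those of line 9 at 0.531 and 0.593, and its 6 day change at 0.284 and 0.351. A test of the difference between lines called 1 probe set in limma, 262128_at, without a listed gene, for line 20 minus line 17 (-10.47 ± 0.72 SE; Benjamini-Hochberg adjusted p = 0.0268), and none for line 17 minus line 9 or line 20 minus line 9 (2594 and 3395 at an unadjusted p under 0.05). It changed by 4.5 and 2.66 in line 9, by 8.37 and 6.35 in line 17, by -1.21 and -5.01 in line 20 and by -3.34 and -1.63 in the empty vector at 3 and 6 days.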

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

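Chosen only after the results were seen were the tests of array kind and estradiol for the flavonoid and autophagy lists, the splits for these single lists, and the splits for the counts at 3 days, in the difference between the days and between the days without inducer.

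Probe set 252984_at was singled out because its induction effect in the amiR-tor lines differed from its estradiol effect in the empty vector, by 2.64 on the log2 scale. Probe set 262128_at was singled out because its induction effect differed between lines 20 and 17, by -10.47. That size is measured in part from levels not shown to be above background. The flavonoid list differed between 6 and 3 days of induction (limma camera adjusted p = 3.72e-06, and adjusted p = 0.135 with an estimated correlation). The autophagy and flavonoid lists differed between the amiR-tor lines and the empty vector (camera adjusted p = 0.000256 and 0.000225, and adjusted p = 0.469 and 0.304 with an estimated correlation). The cytochrome P450 and cyclophilin genes whose symbols start with CYP, and the serine carboxypeptidase-like genes, were lower at 6 than at 3 days of induction (camera adjusted p = 0.0272 for each, 0.138 with an estimated correlation and 0.0961 without line 9). No group has 4 to 10 samples, so no sample was tested for lying apart.

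The higher flavonoid genes were weighed against the kind of array, estradiol and chance. The lowest list median in lines 17 and 20, whose pairs lie within 1 kind of array, was 0.49, against at most 0.19 in the empty vector, so the kind of array is not the whole source. The unadjusted P value of limma's fry, a rotation test, over the list for amiR-tor minus empty vector was 0.0246. The camera adjusted p of the same contrast was 0.304 with an estimated correlation, and the list was picked after its result was seen. These values lean against estradiol as the whole source but do not exclude it. The empty vector also has 1 array per condition and started from a higher DFR level. Of 100 splits of the 12 amiR-tor arrays within days, 5 gave as small a camera p as the real one (5.85e-05, smallest other 2.28e-07). Chance could therefore not be excluded for the list. Of the 13 drawn splits that part the pairs of every line only the real one did, but 13 are too few for a share under 0.05. That limit comes from drawing 100 of the 200 possible splits, and the others were not run. A response to lower TOR stays an open, untested hypothesis, since no probe set was listed for the transcript in the names used here.

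The higher autophagy genes were weighed in the same way. The lowest list median within 1 kind of array was 0.20 in lines 17 and 20 (0.195), against 0.085 and -0.055 in the empty vector. Each is 1 pair of arrays without an estimate of its spread, and the actin difference of line 17 moved at 3 days. Whether the kind of array or the RNA on it is the whole source is therefore not decided. For estradiol, the unadjusted P value of fry was 0.102, and with an empty-vector median of 0.03 neither reading is decided. Of the 100 splits, 9 gave as small a camera p (6.43e-05, smallest other 3.5e-07), so chance could not be excluded. Of the 13 drawn splits that part the pairs of every line only the real one did, but 13 are too few for a share under 0.05. Here too, 100 of the 200 possible splits were drawn and the others were not run. The hypothesis of a response to lower TOR stays open and untested.

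Counts of calls were compared with other splits of the same arrays. Over both days the 390 calls were reached by 1 of 100 splits, the real one, with 16 as the highest other. Most of these splits disregard the pairing by line, and all disregard the kind of array. In the real one both induced arrays of line 9 differ in kind from their controls, so the splits do not exclude chance for that count. Of the 13 drawn splits that part the pairs of every line, the real one alone reached it (highest other 0). With 100 of the 200 possible splits drawn, 13 are too few for a share under 0.05. Averaging the days per line gave 0 calls. At 6 days the real split gave 63 and the highest of the other splits 4, and at 3 days and between days without inducer the real split and the highest other gave 0; with 10 splits each, no share under 0.05 can be reached, and 1, 10 and 10 splits were as large as the real one. For the difference between the days the real count was 0, which any split reaches (100 of 100), so nothing is tested there; other splits gave up to 16 calls, and what these follow was not tested. Of the gene lists, 3 passed at 6 days (highest other 2; 1 of 10 splits as large), and 2 passed over both days, which 37 of 100 splits reached, with 6 as the highest other. Chance is not excluded there, and splits that call more lists than the real one point to a structure of the arrays, which was not tested.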

How the results depend on the processing

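Fits with the 25S class, without line 9 but with the line block, and on the 10 arrays with high 25S signal were chosen after seeing the data. No named value of the induction comparisons that passed the threshold changed direction under the scalings, blocks, left-out lines and 25S fits. Of 528 tests of the 11 fixed lists under alternatives 25 changed direction, 0 of them past the threshold in either fit, among them the root markers at 6 days (adjusted p = 0.43 without line 9, in a range of 0.278 to 0.659 without each line, and 0.705 with the 25S class) and over both days (0.981 with the class) and photosynthesis between the days (0.954 without line 17, in a range of 0.000792 to 0.954 without each line). Without the filter on dim probe sets the calls numbered 4 at 3 days, 8 at 6 days, 88 over both days, 297 for estradiol in the empty vector, 274 for amiR-tor minus empty vector, 215 for the non-induced lines minus empty vector and 46 between lines; 280, 253 and 186 of the 297, 274 and 215 were dim probe sets near the floor. The stricter filter and eBayes with trend and robust each gave 1 call at 3 days. With the 25S class as a covariate there were 30 calls at 6 days, 61 over both days, 0 for amiR-tor minus empty vector and 1 between days without inducer; with the class and the line block, 148 over both days and 0 for amiR-tor minus empty vector. Without line 9 but with the line block, there were 29 calls at 6 days, 43 over both days, 0 for amiR-tor minus empty vector and 532 between days without inducer. Only the 6 arrays compared gave 2 calls at 6 days, the 10 arrays with high 25S signal 0, days averaged per line 0 over both days, and the 2-fold requirement 163 over both days; the first 2 used fewer arrays and the third fewer values, 1 difference per line, and otherwise the cause was not tested. The line block gave 0 calls for amiR-tor minus empty vector, 65 at 6 days and 571 over both days, and changed no other count by over 1.5 times. Leaving out each line gave 1 to 55 calls at 6 days, 1 to 379 over both days, 0 for amiR-tor minus empty vector, 0 to 33 for the non-induced lines minus empty vector, 0 to 310 between days without inducer, and 8 to 19 list calls. The 11 list calls were 0 with an estimated correlation. Of 27 called values of named genes, 26 stayed past the threshold with quantile normalization, 26 with median-centring, 27 with trend, 24 with the line block, 0 without line 9, 0 without line 17, 20 without line 20 and 8 with the 25S class. Rescaling moved the median of no array by more than 0.04. Values near the floor limit what can be seen of dim genes.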

Other observations

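The families below were chosen after the data were seen, and for the size of line 9's response the criterion was tightened after its value was seen, by asking that the quartiles of the gap lie on 1 side of 0.

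Beyond the fixed lists, the 9 VPS genes of vacuolar sorting had a median change of 0.32 over both days of induction, 8 of them positive, and VPS60.2 rose by 0.74 (limma, Benjamini-Hochberg adjusted p = 0.028). As a set they were not past the threshold (camera adjusted p = 0.0747, and 0.0345 with the 25S class as a covariate). The 62 measured genes encoded in the plastid had a median of -0.14 over both days (camera adjusted p = 0.145, and 0.0125 without line 9), which was 0.23 with the 25S class as a covariate, where the test pointed up (0.846). They had a median of -0.48 in the non-induced lines minus the non-induced empty vector (0.0225; adjusted p = 0.904 with an estimated correlation), which was -0.13 with the class, where the test pointed up (0.783). Between 3 and 6 days without inducer their median was -0.01 with the test pointing up (camera adjusted p = 0.631), -0.41 with the class (down, 7.6e-05) and 0.68 without line 9 (up, 6.04e-16), so the direction depends on the fit. The 10 PRA genes had a median of -0.22 in the non-induced lines minus the non-induced empty vector (camera adjusted p = 0.0225; adjusted p = 0.384 with an estimated correlation).

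Line 9 changed at more probe sets than lines 17 and 20, and 2 hypotheses were tested. Its change correlated across probe sets with the 3 minus 6 day difference of the non-induced arrays of lines 17 and 20, where the kind of array also changes, at r = 0.589, against -0.014 with the same day difference of the empty vector, whose arrays are of 1 kind. A difference in the arrays or the RNA on them may therefore account for much of line 9's excess. Over 29 probe sets called at 6 days from lines 17 and 20 alone, line 9's median change in the called direction was 2.01, against 1.85 and 1.75 in lines 17 and 20; line 9 exceeded both in 13 of them, with quartiles of the gap from -1.15 to 0.57. The 29 were chosen by their changes in lines 17 and 20, which can raise the medians of those lines but not that of line 9. Whether line 9 also responds more strongly cannot be told apart from the kind of array with these arrays.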
